A study of Mus musculus with 46 samples.

How the data were processed

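RNA sequencing and chromatin immunoprecipitation sequencing with an antibody to LMO2 were carried out on T cells of wild-type mice and of mice that carry an LMO2 transgene under control elements of human CD2, all of the C57BL/6 strain per the labels. LMO2 is a bridging protein of transcription factor complexes in blood stem cells, and its gene is a known oncogene of T-cell leukaemia. There were 40 RNA libraries and 5 ChIP libraries with values. An input library of transgenic total thymocytes, also listed in the labels, was not analysed here.

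The RNA values are deposited read counts per gene for 19521 genes. They are whole numbers, and their sums per library were between 17211426 and 28842773. The authors gave FPKM values of the same libraries beside the counts, which were not used here. The submitters' processing notes name HISAT, DESeq2, Bowtie2 and MACS2, and the builds mm10 and mm9, without saying which step used which. Versions, the counting tool and trimming are not given in the sources used here. Among the gene symbols, 25 had been turned into dates and 2 symbols were given more than once, so each gene was followed by its identifier. The table also holds 4 columns, of which 2 are counts, for samples that are not analysed here. The names of 12 of the 40 count columns end in the letter N, whose meaning the labels do not give.

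The ChIP values are peak lists, 1 library per cell type. The deposited fold of each peak is the ratio of its summit to the peak caller's background. The deposited -log10 p of each peak has a lowest value of 2.0, and the deposited -log10 q of most peaks is 0. The column order and names are those of MACS2, per the submitters' processing notes the tool named for peaks. Coordinates are taken as mm9 from the chromosome names, and the control used for peak calling is not given in the sources used here.

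Libraries were grouped by genotype and stage from the labels. The thymic stages are CD4 and CD8 double-negative cells (DN), their DN1 and DN3 subsets, double-positive cells (DP), and CD4 and CD8 single-positive cells (CD4SP, CD8SP). DN3, total DN, DP, CD4SP and CD8SP had 3 libraries per genotype. DN1 had 3 transgenic libraries and 1 wild-type library, and splenic CD4 and CD8 T cells had 3 libraries each from transgenic mice. The groups, the tests, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined.

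Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the robust quasi-likelihood test was used, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each genotype comparison used the 6 libraries of its stage. DN1 used a fit of all 40 libraries, because wild-type DN1 has 1 library, whose spread is assumed to be that of the other groups. Whether the genotype effect differs between DN3 and DP, and between CD4SP and CD8SP, was tested by an interaction term over 12 libraries. Splenic CD4 cells were compared with transgenic CD4SP, splenic CD8 cells with transgenic CD8SP, and splenic CD8 with splenic CD4 cells. Log2 fold changes come from the fit with a prior count of 0.125, and levels are given as CPM, the read count scaled by the TMM library size. Equal replicate numbers in the 2 genotypes are not said to share a litter or day, so no block was used in the tests reported. A fit with a replicate block is given beside each count of changed genes except DN1, and for gene lists where it changes a call.

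Changes of 26 gene lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the lists within a comparison. They cover T-cell stages and signalling, leukaemia genes, partners of LMO2, cell division, DNA repair and cell death, interferon responses, markers of other cell types, and ribosomal and stress genes. Camera with an estimated correlation and fry were run beside it. Lmo2 itself was left out of every list. Because 3 against 3 libraries can be split in 10 ways, no exact test on them can give a p under 0.1. With 10 splits, non-overlap of the groups in a given gene has a chance share of 10% for 3 against 3.

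Genes to be named were fixed by rule. Lmo2 came first. Genes past the threshold whose groups did not overlap, with a mean CPM of at least 5, gave the 10 largest increases and the 10 largest decreases per genotype comparison, and 5 each for the spleen, DN1 and interaction comparisons (for interactions without the condition on overlap). Predicted genes, receptor and immunoglobulin segments, pseudogenes and small RNAs were left out. Up to 4 members of each list with the smallest adjusted p were added, and the 10 genes with the largest mean change for the genes shared by all stages. Where one group held 3 counts or fewer of a gene, the CPM of both groups are given and no fold change.

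The tests were checked on simulated counts with the depth and spread of these libraries, 200 genes being changed in each set. At a log2 change of 2, edgeR found 96% of them in DN3, 77% in total DN, 84% in DP, 70% in CD4SP and 89% in CD8SP. At a log2 change of 1 the shares were 83%, 43%, 40%, 7% and 34%. False calls were 11 of 190 calls in DN3, 7 of 127 in DN, 4 of 128 in DP, 1 of 78 in CD4SP and 15 of 138 in CD8SP. For splenic CD4, splenic CD8 and between the splenic lineages, 37%, 55% and 48% were found at a log2 change of 2. At a log2 change of 1 these shares were 1%, 5% and 5%, and false calls were 2 of 40, 11 of 71 and 6 of 59. DESeq2 1.42.0 gave 40 false calls of 224 in the DN3 set.

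Peaks were compared with bedtools 2.31.1 and Python 3.11.15. A shared peak overlaps by at least 1 bp. The share expected was taken from 100 random placements of the same peaks on the same chromosomes. Shares carry exact binomial 95% intervals (Clopper-Pearson, scipy 1.17.1), which cover counting error only, since reads amplified by PCR are not independent molecules. The total reads of the ChIP libraries are not known, and no genome or gene annotation of mm9 was used here. Shares of peaks at start sites, motif shares and the joining of peaks to genes were therefore not computed.

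The alternatives were DESeq2, size factors in place of TMM, no filter, a filter at a mean CPM of 1, a replicate block, each library left out in turn, a fit of all 40 libraries together, stricter peak lists and other list tests. Others were added after the data were seen. These are a term for the letter N and fits without libraries whose sort markers or blood transcripts stood apart. Other splits of the same samples were also counted.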

Results

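The samples were sorted T cells of wild-type mice and of mice with an LMO2 transgene, at stages from early thymic precursors to splenic T cells. RNA was counted in 40 libraries, with totals of 17211426 to 28842773 reads per library over 19521 genes. Wild-type and transgenic DN3, total DN, DP, CD4SP and CD8SP cells had 3 libraries each. DN1 had 3 transgenic libraries and 1 wild-type library, and transgenic splenic CD4 and CD8 T cells had 3 libraries each. Anti-LMO2 ChIP was given for 5 cell types, 1 library each. The labels set stage-matched genotypes side by side, so the first question is what differs in the transcripts of each stage when LMO2 is kept on. Below, fold changes are transgenic over wild type on a log2 scale with their standard error, levels are CPM with the SD over 3 libraries, and adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

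Lmo2 (identifier 16909), the gene of the transgene, was low in wild-type cells past the DN1 stage and high in transgenic cells of every stage, 1 DP library excepted. Its level was 31.7 CPM in the wild-type DN1 library, 4.06 ± 0.375 in wild-type DN, and 0.239 ± 0.0417 in wild-type DN3. In transgenic cells it was 40.1 ± 4.54 in DN1, 20.6 ± 5.82 in DN, 21.5 ± 3.42 in DN3, 46.3 ± 26.5 in CD4SP, 50.1 ± 18.9 in CD8SP, 60.2 ± 23.4 in splenic CD4 and 61.4 ± 26.3 in splenic CD8 cells. The counts are of the mouse gene, and whether the transgene is of mouse or human sequence is not given in the sources used here. Lmo2 rose by 6.47 ± 0.24 in DN3, 2.29 ± 0.26 in DN, 4.92 ± 0.55 in CD4SP and 6.68 ± 0.54 in CD8SP, with adjusted p of 9.99e-07, 0.00338, 0.0058 and 0.00337 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The increases in CD4SP and CD8SP each kept that call in 5 of 6 fits that left out 1 library. In DP the log2 fold change was 7.5 ± 1.7 with an adjusted p of 0.213 in that test, because the transgenic libraries stood apart: 78.8 and 70.0 CPM in replicates 1 and 2, and 0.395 CPM in replicate 3, against 0.276 ± 0.18 in wild-type DP. In DN1 it was 0.34 ± 1.01.

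**Figure D1:**
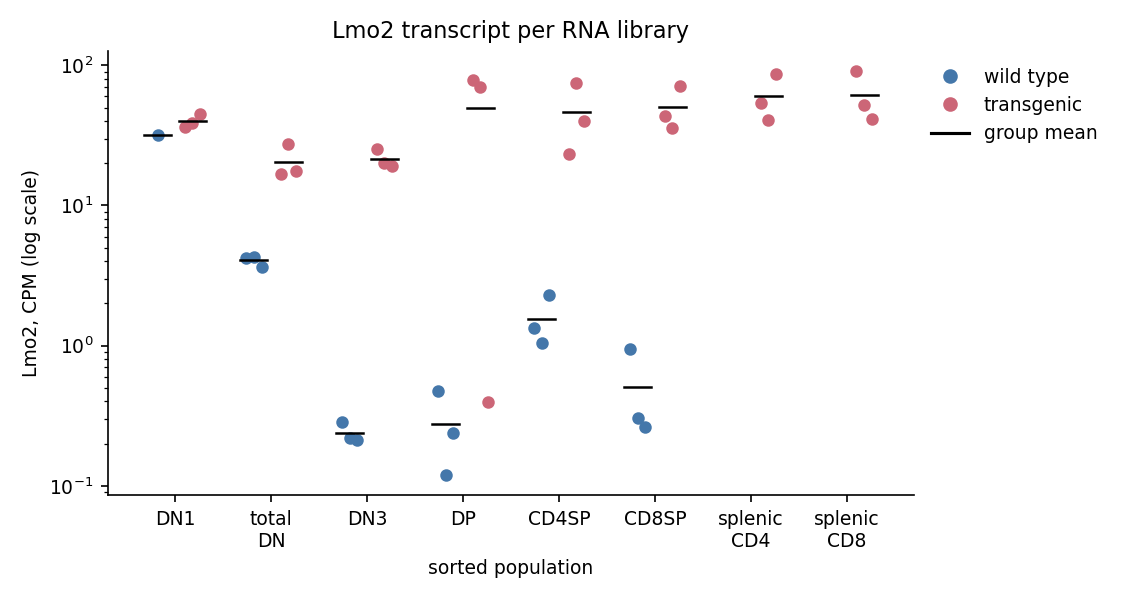
Lmo2 in CPM (log axis) in each RNA library by stage, 1 point per library, for wild-type and transgenic cells, with a line at the mean of each group. Transgenic DP replicate 3 lies at 0.395 CPM, beside wild-type DP, while the other transgenic DP libraries lie at 78.8 and 70.0 CPM.

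The DN3 comparison asks what differs at the stage where T-cell receptor beta chains are selected. Hhex, a homeobox gene of stem cells and early progenitors, rose by 6.82 ± 0.32 from 1.10 ± 0.608 to 125 ± 23.9 CPM. Lyl1, a helix-loop-helix partner of LMO2, rose by 6.72 ± 0.60, and Kit, the stem cell factor receptor, by 2.52 ± 0.20. The largest increases also held Tenm4 at 10.47 ± 0.59, Faxc at 9.21 ± 0.77, Olfm5 at 8.84 ± 0.56, Acox2, a peroxisomal oxidase, at 8.78 ± 0.36, and Gpr82 at 8.44 ± 0.66. Tbx4, a T-box factor of limb and lung, was at 110 ± 20.1 CPM in transgenic DN3 and 0.0239 in wild type. Among the largest decreases Bcl11a, a zinc-finger factor of lymphoid progenitors, fell by 7.90 ± 0.35, Adam11 by 7.19 ± 0.23, Adamtsl2 by 6.70 ± 0.25, the inflammatory caspase Casp1 by 6.20 ± 0.30 and the cell cycle inhibitor Cdkn1a by 5.08 ± 0.49. Adjusted p of these genes was between 3.07e-07 for Tbx4 and 0.000276 for Cdkn1a in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

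By the lists fixed in advance, 4 of 26 moved as a group in transgenic DN3. Of 27 genes of pre-TCR and TCR signalling 18 rose and 5 fell, the same counts when adjusted over the list alone: Cd6 rose by 2.54 ± 0.11 and the kinase Zap70 by 1.65 ± 0.12, and the receptor chain Cd3g fell by 1.62 ± 0.12. Of 27 T-cell leukaemia oncogenes and tumour suppressors 14 rose and 3 fell (15 and 4 adjusted over the list alone), among them Etv6 at 1.42 ± 0.11 and Stat5b at 1.24 ± 0.11, while Mef2c fell by 5.43 ± 0.49. All 3 measured mast-cell and basophil markers rose (3 adjusted over the list alone), namely Kit, the protease Cpa3 at 3.85 ± 0.40 and the histamine-forming enzyme Hdc at 2.74 ± 0.56. Of 5 dendritic-cell markers 4 fell (4 adjusted over the list alone), namely the chemokine receptor Ccr9 by 3.06 ± 0.23, Irf8 by 0.91 ± 0.16, Bst2 by 0.72 ± 0.15 and Ly6d by 1.21 ± 0.25. Camera's adjusted p was 5.55e-05, 0.000296, 0.00118 and 0.0111 for these lists, and each was lost at an adjusted p = 0.238 with an estimated correlation.

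The other 22 lists did not pass camera's threshold in DN3, at adjusted p of 0.0732 or more, though many members changed. With a replicate block LMO2 partners and mature and naive genes passed upward, at adjusted p of 0.0144 and 0.01. Of 13 LMO2 partners 9 rose and 3 fell, Lyl1 and Cbfa2t3 (0.89 ± 0.13) among the former. Of 18 stem and progenitor genes 6 rose and 7 fell, with Hhex up and Hoxa7, a homeobox gene, down by 7.23 ± 0.49. Notch targets and DN3 genes went both ways, 8 up and 6 down of 18, Heyl rising by 2.75 ± 0.33 and Spib falling by 2.28 ± 0.16. Of 25 interferon-stimulated genes 2 rose and 10 fell, with Oas3 up by 1.22 ± 0.14 and Gbp3 down by 1.10 ± 0.17, and Ifi44 was at 0.0229 CPM against 10.9 in wild type. Mature thymocyte and naive T-cell genes gave 11 up, such as Lef1 at 1.32 ± 0.12, and 2 down of 24, H2-Q7 falling by 4.82 ± 0.18. Among genes of V(D)J recombination, which assembles receptor genes, 1 of 12 rose and 5 fell, the recombinase subunit Rag2 by 2.95 ± 0.30. Immediate-early and stress genes gave 10 up and 3 down of 21, CD4 lineage genes 6 up and 1 down of 13, CD8 lineage genes 3 up and 2 down of 8, DP thymocyte genes 6 up and 4 down of 20, and effector, memory and exhaustion genes 2 up and 6 down of 12. Gamma-delta and NKT markers gave 2 up and 4 down of 8, p53 targets 6 up and 3 down of 20, and apoptosis regulators 4 up of 18.

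Little moved in DN3 in genes of cell division and of the ribosome: 1 of 34 cell cycle genes and 3 of 32 ribosomal protein genes fell, and adjusted over the list alone no ribosomal gene passed. Double-strand break repair genes gave 2 up of 26. Among markers of other cells, B-cell markers gave 2 down of 7, myeloid markers 1 up and 3 down of 8, NK and innate lymphoid markers 2 up and 3 down of 6, erythroid and megakaryocyte markers 1 up of 10, and thymic stroma markers 2 up and 2 down of 8. Adjusted over the list alone, the calls were 3 up and 14 down for interferon-stimulated genes, 7 and 8 for stem and progenitor genes, 7 and 4 for DP genes, 2 and 5 for gamma-delta genes, 1 and 0 for repair and 0 and 0 for erythroid genes, and for the rest as given over all genes.

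In all, 5497 of 12037 genes changed between transgenic and wild-type DN3, 2822 up and 2675 down, with 1011 and 925 of them by 2-fold or more. A fit with a replicate block gave 5176, and leaving out 1 library gave between 3802 and 6185. One fit of all RNA libraries together called fewer genes than any of these, as given with the other alternatives below. Of the 99 named genes past the threshold 89 kept it in each of these 6 fits.

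Total DN cells, which hold DN3 and the stages around it, shared many of these changes: 621 genes rose and 367 fell in both, where 217 and 129 were expected if the calls were independent. Acox2 rose by 8.79 ± 0.65, the LIM protein gene Lmcd1 by 8.76 ± 0.60, and Ryr2, a calcium channel of muscle, by 8.24 ± 0.65, and Tbx4 was at 65.3 CPM against 0.0222. The stem cell factors Hhex, Nfe2 and Erg rose by 4.46 ± 0.47, 4.34 ± 0.37 and 2.50 ± 0.19. Cdkn2a, which encodes a brake on cell division and an activator of p53, rose by 7.02 ± 0.82. The decreases held Arhgap32 by 5.57 ± 0.56, the stress kinase gene Map3k20 by 5.12 ± 0.32, Hoxa7 by 5.52 ± 0.52 and the heat-shock genes Hspa1b by 2.08 ± 0.21 and Hspa1a by 2.64 ± 0.37. Each of these genes kept its call whichever of the 6 libraries was left out, and their adjusted p was between 2.75e-05 for Tbx4 and 0.00752 for Hspa1a in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

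Of 14 LMO2 partners 5 rose in total DN and none fell (8 and 1 adjusted over the list alone), led by Lyl1 at 4.53 ± 0.67 and Gata1, the erythroid and mast-cell factor, at 2.54 ± 0.45. Of 3 mast-cell markers 2 rose (2 adjusted over the list alone), Cpa3 by 5.59 ± 0.77 and Kit by 2.0 ± 0.34. Of 20 DP thymocyte genes 1 rose and 6 fell (1 and 8 adjusted over the list alone), Rag2 by 2.88 ± 0.41 and Ccr9 by 1.77 ± 0.32. Of 22 immediate-early and stress genes 1 rose and 3 fell (1 and 7 adjusted over the list alone). Camera called these 4 lists at adjusted p of 0.0248, 0.0248, 0.0235 and 0.00492, and all were lost at an adjusted p = 0.765 with an estimated correlation. Wild-type DN replicate 3 held 9004 CPM of the haemoglobin gene Hba-a1, a transcript of red cells, and the erythroid list had a median log2 fold change of -2.82 with 1 of 12 members called.

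The DN count was 1547 of 12509 genes, 935 up and 612 down, and it moved with single libraries. It was 3146 without transgenic replicate 2, 371 without transgenic replicate 3, and 252, 179 and 888 without wild-type replicates 1, 2 and 3. A replicate block gave 1494. The column suffix N is carried by transgenic replicates 1 and 3 and by no wild-type DN library. With a term for it transgenic replicate 2 alone stands against wild type, so no count is given. Of 70 named genes past the threshold 22 kept it in every leave-one-out fit. Lyl1, Gata1, Cpa3, Kit, Rag2 and Ccr9 were not among the 22: of the 6 fits Lyl1, Cpa3 and Rag2 kept their call in 4, Gata1 and Kit in 3, and Ccr9 in 2.

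In DP cells, the stage of receptor alpha-chain rearrangement, no gene of 11649 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2450 had an unadjusted p under 0.05, and DESeq2 called 605. With transgenic replicate 3 left out, a choice made after its Lmo2 level was seen, 906 genes changed, 569 up and 337 down. A replicate block gave 0 genes with 3 libraries each, and so did a term for the suffix N.

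Without that replicate, Notch target genes stood out among the DP increases. The ubiquitin ligase gene Dtx1 rose by 4.82 ± 0.25, Hes1 by 4.01 ± 0.40, Notch1 by 2.06 ± 0.16 and Ptcra, the pre-TCR alpha chain, by 1.80 ± 0.16. Transgenic DP replicate 2 held transcripts of DN3 cells at an implied share of 7.82%, with Cpa3 at 174.5 CPM against 3.51 in replicate 1. Dtx1, Hes1, Notch1 and Ptcra stood at 541.5, 5.58, 1151 and 140.1 CPM in replicate 1, and at 420.2, 6.44, 1022 and 121.1 in replicate 2. Bst1 rose by 7.33 ± 0.49, Mzb1 by 6.60 ± 0.43, Arhgef10l by 6.40 ± 0.38, and the CD8-lineage factor Runx3 by 1.93 ± 0.21. The DNA sensor Aim2 fell by 6.48 ± 0.56, Adam12 by 6.13 ± 0.49, and Rag2 by 1.24 ± 0.23. Adjusted p of these genes was between 0.000621 for Dtx1 and 0.0339 for Rag2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In this fit 8 of 18 Notch targets, 8 of 34 cell cycle genes, 6 of 32 ribosomal protein genes and 4 of 9 CD8 lineage genes rose and none fell (9, 17, 22 and 6 up adjusted over the list alone). Camera's adjusted p was 9.83e-13, 1.47e-05, 2.53e-08 and 0.000383, lost at an adjusted p = 0.325, 0.851, 0.437 and 0.325 with an estimated correlation.

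With all DP libraries camera called 6 lists upward: Notch targets, cell cycle, ribosomal protein, CD8 lineage, effector and mast-cell genes. Their adjusted p was 6.93e-06, 4.98e-07, 5.26e-08, 1.91e-05, 6.81e-05 and 0.0455, with 9, 7, 0, 6, 7 and 2 members up when adjusted over the list alone. These were lost at an adjusted p = 0.655, 0.667, 0.667, 0.534, 0.603 and 0.603 with an estimated correlation, in the same order. The mast-cell call was also lost with a replicate block, at an adjusted p of 0.0775.

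In CD4SP cells, the mature helper branch of the thymus, interferon-inducible genes fell and cell division genes rose. Arhgap29 fell by 7.05 ± 0.50, Gbp10, an interferon-induced GTPase gene, by 5.27 ± 0.48 and the activation marker Cd69 by 2.70 ± 0.32, and Tbx4 was at 40.9 CPM against 0.013. These 4, and Arhgap20 at -4.86 ± 0.53, kept their calls in every leave-one-out fit, and the other genes named for CD4SP lost theirs without wild-type replicate 1, where 38 genes passed. All 34 cell cycle genes rose (34 adjusted over the list alone), with Aurka at 2.91 ± 0.36 and Plk1 at 3.02 ± 0.39. Of 25 interferon-stimulated genes 15 fell (21 adjusted over the list alone), Ifit1 by 2.87 ± 0.36 and Rtp4 by 1.89 ± 0.25. Mature thymocyte and naive genes fell in 8 of 24 (9 adjusted over the list alone), CD4 lineage genes in 5 of 13 (5 adjusted over the list alone), with Ctla4 down by 3.24 ± 0.58, and immediate-early genes in 8 of 20 (9 adjusted over the list alone), with Junb down by 3.05 ± 0.55. Notch targets gave 6 up and 1 down of 19 (7 and 1 adjusted over the list alone), with Notch3 at 4.41 ± 0.55 and Notch1 at 1.29 ± 0.22.

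Genes of DP cells and of other lineages were also higher in transgenic CD4SP. Of 20 DP genes 9 rose (12 adjusted over the list alone), with the terminal transferase Dntt at 3.61 ± 0.54. B-cell markers rose in 8 of 10 (10 adjusted over the list alone), with Cd79b at 3.47 ± 0.43, myeloid markers in 9 of 13 (12 adjusted over the list alone), with the lysozyme gene Lyz2 at 2.63 ± 0.57, and stem and progenitor genes in 9 of 18 (11 adjusted over the list alone), with Spi1 at 3.75 ± 0.73. Double-strand break repair genes gave 14 up and 3 down of 26 (16 and 3 adjusted over the list alone), with H2afx at 2.91 ± 0.30, and LMO2 partners 5 up and 1 down of 13 (5 and 1 adjusted over the list alone), with Cbfa2t3 at 4.34 ± 0.61. Without wild-type replicate 1, where 38 genes passed, none of these genes kept its call. The sort markers of these libraries differed too: transgenic replicate 1 held 190 CPM of Cd4, 183 of Rag1 and 347 of Il2ra, and transgenic replicate 2 held 3093 CPM of Cd8a and 6487 of Rag1. In transgenic replicates 1 and 3, 25 transcripts abundant in transgenic DN3 stood, at the median, where shares of 63.1% and 39.2% of DN3 cells would put them.

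Camera called these 12 lists in CD4SP, at adjusted p from 2.53e-24 for cell cycle and 2.07e-10 for interferon-stimulated genes to 0.0441 for LMO2 partners and Notch targets. All were lost at an adjusted p = 0.511 with an estimated correlation, or 0.668 for stem and progenitor genes and 0.548 for Notch targets. In total 3132 of 12073 genes changed, 1807 up and 1325 down, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 38, 100 and 1481 without wild-type replicates 1, 2 and 3, and 1362 with a replicate block. Only transgenic replicates 1 and 3 carry the suffix N here. With a term for it transgenic replicate 2 alone stands against wild type, so no count is given. Adjusted p of the named genes in edgeR's quasi-likelihood test was between 0.00138 for Tbx4 and 0.0472 for Cd8a. Of 96 named genes past the threshold 5, 15 and 59 kept it without wild-type replicates 1, 2 and 3, and 78, 95 and 85 without transgenic replicates 1, 2 and 3.

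In CD8SP cells, the cytotoxic branch, genes of mature and cytotoxic T cells fell. Those of the mature and naive list fell in 8 of 24 (15 adjusted over the list alone), with the chemokine receptor Ccr7 down by 2.37 ± 0.32 and the interleukin 7 receptor Il7r by 1.73 ± 0.27. CD8 lineage genes fell in 5 of 13 (9 adjusted over the list alone), with Dapl1 down by 4.28 ± 0.45 and the perforin gene Prf1 by 2.09 ± 0.30. Interferon-stimulated genes fell in 9 of 25 (19 adjusted over the list alone), with Oas1a down by 2.55 ± 0.35 and Irf7 by 1.57 ± 0.27, and immediate-early genes in 3 of 20 (3 adjusted over the list alone), with Junb down by 1.61 ± 0.22. Among the largest increases were Yap1, a growth regulator, at 6.91 ± 0.47, Bst1 at 5.86 ± 0.46 and Mzb1, a chaperone of plasma cells, at 5.49 ± 0.30, and Tbx4 was at 38.3 CPM against 0.0167. Cd72 and St3gal6 fell by 4.47 ± 0.41 and 3.84 ± 0.26. Without wild-type replicate 2, where 9 genes passed, the genes named for CD8SP lost their calls except Tbx4, Yap1, Mzb1, Cd72 and St3gal6.

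Notch targets rose in 3 of 19 measured genes in CD8SP (7 up and 2 down adjusted over the list alone), with Notch1 at 1.31 ± 0.16, Notch3 at 1.84 ± 0.33 and Heyl at 4.96 ± 0.49. Cell cycle genes rose in 2 of 34 (2 adjusted over the list alone), leukaemia genes in 3 with 1 down of 27 (6 and 1 adjusted over the list alone), gamma-delta markers in 1 of 7 (3 adjusted over the list alone), LMO2 partners in 1 of 13 (3 adjusted over the list alone), and no ribosomal gene of 32 was called over all genes or adjusted over the list alone. Camera called these 10 lists. Its adjusted p was 1.23e-15 for interferon-stimulated, 2.19e-12 for mature and naive, 2.64e-10 for CD8 lineage, 8.53e-06 for immediate-early, 0.000804 for ribosomal (downward), and 3.33e-07 for cell cycle genes. It was 0.000394 for Notch targets, 0.00657 for leukaemia genes, 0.0106 for gamma-delta markers and 0.0119 for LMO2 partners. All were lost at an adjusted p = 0.209 to 0.812 with an estimated correlation.

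The CD8SP total was 520 of 11697 genes, 244 up and 276 down, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was 285 without transgenic replicate 1, and 18, 9 and 329 without wild-type replicates 1, 2 and 3. A replicate block gave 798 and the suffix term 469, and adjusted p of the named genes was between 0.000251 for Tbx4 and 0.046 for Plk1. Of 51 named genes past the threshold 8, 5 and 40 kept it without wild-type replicates 1, 2 and 3, and 33, 41 and 46 without transgenic replicates 1, 2 and 3. Tbx4, Yap1, Mzb1, Cd72 and St3gal6 kept it in every one of these fits. Replicate 3 of both genotypes held DP transcripts, with 1408 CPM of Cd4 in the transgenic and 855 in the wild-type library, and 6083 and 3025 CPM of Rag1.

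**Figure D2:**
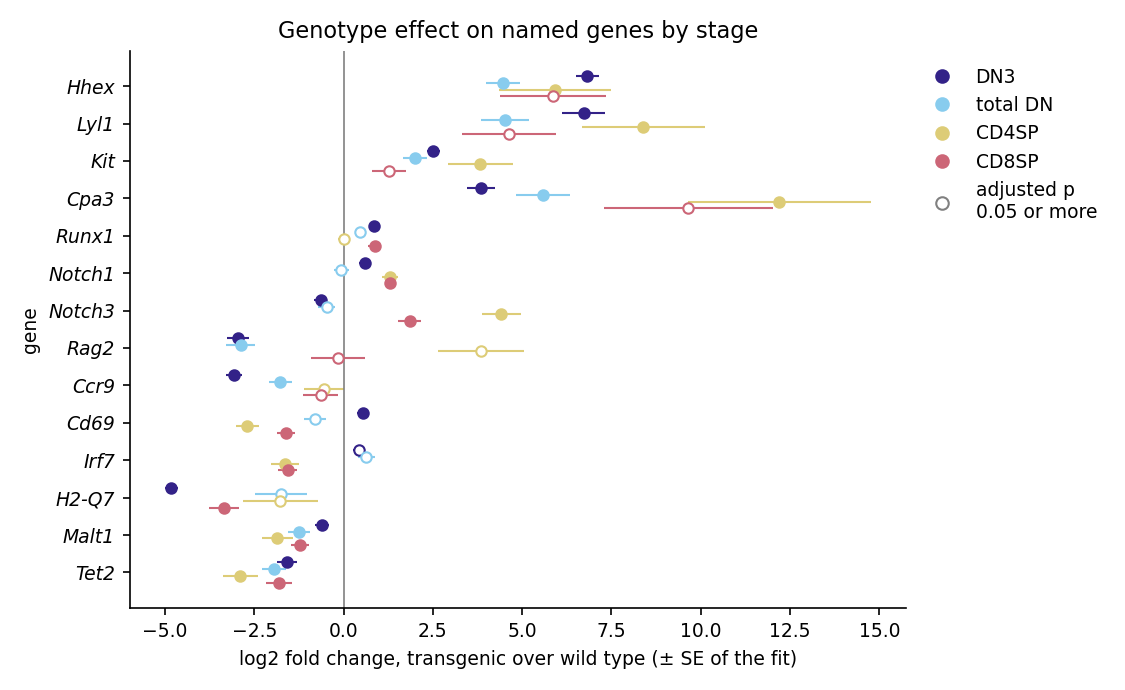
Log2 fold change, transgenic over wild type, of 14 genes at DN3, total DN, CD4SP and CD8SP, with bars of 1 standard error and open symbols where the adjusted p is at least 0.05. The genes were chosen after their values were seen. Notch1 rose by 1.29 in CD4SP and 1.31 in CD8SP, and Malt1 was below 0 at each of these stages.

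In DN1 cells, the earliest thymic stage, no gene of 14845 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 157 had an unadjusted p under 0.05, and DESeq2 called 3. Wild-type DN1 has 1 library, so its spread is assumed to be that of the other groups. Camera called B-cell markers, immediate-early genes and ribosomal protein genes downward at adjusted p of 7.24e-07, 3.29e-08 and 0.0114, with no member past the threshold over all genes. They were lost at an adjusted p = 0.715, 0.307 and 0.991 with an estimated correlation. These list values cannot separate genotype from the make-up of that 1 library, which held 517 CPM of the B-cell gene Cd79a against 393, 248 and 271 in the transgenic libraries.

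Genes changed in the same direction at every stage were counted next, without a test of what makes them shared. Over DN3, total DN, CD4SP and CD8SP, 107 genes rose and 24 fell at each, where 0.596 and 0.279 were expected if the calls were independent, among 11262 genes tested at all of them. Yap1, Dlx1, Olig3, Mzb1 and Lmo2 were among the former. The calls of these stages are not independent, so the expected numbers do not measure chance. Total DN holds DN3 cells, and transgenic CD4SP replicates 1 and 3 held transcripts of DN3 cells. Genes of chromosome 15 were called up more often than other genes at each of these stages, as given below. Tet2, which oxidises methylated DNA, fell by 1.59, 1.94, 2.90 and 1.81 at these stages. The shared count rests on single libraries: CD4SP had 38 calls without wild-type replicate 1, and CD8SP 18 and 9 without wild-type replicates 1 and 2, and no more genes than that can be shared in such fits. These genes were chosen after their values were seen. With DP added the count was 0 of 11109 genes, since edgeR called none in DP, where 2450 had an unadjusted p under 0.05, and it was 0 with a replicate block too. With DESeq2's calls at all 5 stages it was 105, and with DP called without transgenic replicate 3 it was also 105.

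Whether the transgene acts differently before and after the DN3 to DP step was tested by the interaction. Adam11 and Cdh1, the E-cadherin gene, had interactions of 6.93 ± 0.65 and 6.57 ± 0.63. Cdkn1a, at 7.47 ± 1.06, fell by 5.08 in DN3 and had a log2 fold change of 2.36 in DP. F2r, a thrombin receptor gene, and the adenylate cyclase gene Adcy9 had interactions of -4.98 ± 0.33 and -4.21 ± 0.41, having risen by 5.03 and 4.56 in DN3 against 0.03 and 0.32 in DP. The interaction passed for 1266 of 12451 genes, 607 positive and 659 negative, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and adjusted p of the named genes was between 2.99e-05 for F2r and 0.0304 for Bst1. Pre-TCR and TCR signalling genes were negative in 10 of 27 and positive in 1 (14 and 4 adjusted over the list alone), and dendritic-cell markers positive in 4 of 8 (6 adjusted over the list alone). Camera's adjusted p was 0.000529 and 3.38e-05, and both were lost at an adjusted p = 0.426 and 0.108 with an estimated correlation. They are part of 9 lists that camera called upward and 4 downward in this interaction, 0 of them kept with an estimated correlation.

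That DN3 to DP count rests on both groups' libraries. It was 539, 655 and 607 without transgenic DN3 replicates 1, 2 and 3, and 364, 2009 and 352 without wild-type DN3 replicates 1, 2 and 3. It was 759 and 2598 without transgenic DP replicates 1 and 3, and 589 and 555 without wild-type DP replicates 2 and 3. A replicate block gave 1549 and the suffix term 1991, and 7 of the 10 named genes kept their call in all 12 leave-one-out fits. The other 3 were Bst1, Slc40a1 and St8sia6, which kept it in 5, 10 and 6 of the 12.

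Between the CD4SP and CD8SP branches the genotype effect differed for 4 of 12507 genes. Zfp281, a zinc-finger factor, had an interaction of 1.96 ± 0.20, as it fell by 2.22 in CD4SP and had a log2 fold change of -0.27 in CD8SP. Mcoln2, a lysosomal channel gene, had an interaction of -3.50 ± 0.45, Cxxc5 of -2.75 ± 0.36, and 1500009L16Rik, chosen after its values were seen, of -4.21 ± 0.57. Adjusted p was 0.00881, 0.0379, 0.0379 and 0.0409 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2067 genes had an unadjusted p under 0.05. Cell cycle genes were lower as a group at camera's adjusted p of 1.74e-35, with 0 of 34 members past the threshold over all genes and 34 adjusted over the list alone, and this was lost at an adjusted p = 0.502 with an estimated correlation. Between the branches camera called 2 lists upward and 8 downward, and 0 were kept with an estimated correlation. Transgenic CD4SP replicates 1 and 3 held transcripts of DN3 cells at implied shares of 63.1% and 39.2%. A difference between the branches therefore cannot be told apart from cells of other stages in these libraries.

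The branch count moved with nearly every library. It was 1, 130 and 611 without transgenic CD4SP replicates 1, 2 and 3, 1 without each of the transgenic CD8SP replicates 1, 2 and 3, 0, 0 and 103 without wild-type CD4SP replicates 1, 2 and 3, and 0, 1 and 0 without wild-type CD8SP replicates 1, 2 and 3. DESeq2 called 694, a replicate block gave 0 with 1841 at an unadjusted p under 0.05, and the suffix term gave 1. Zfp281 kept its call in 8 of 12 such fits, and Mcoln2 and Cxxc5 in 3 each.

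Splenic T cells were compared with their thymic counterparts within the transgenic mice, to ask what differs after export. No wild-type splenic library was among the samples, so an effect of Lmo2 cannot be told apart from the step from thymus to spleen. Lmo2 itself differed by 0.37 ± 0.46 in CD4 and 0.22 ± 0.39 in CD8 cells. In splenic CD4 cells, 33 of 34 cell cycle genes were lower (34 adjusted over the list alone), Cdc6 by -3.34 ± 0.42, as were 14 of 20 DP genes (15 adjusted over the list alone), Dntt by -7.42 ± 0.38 and the receptor Notch3 by -5.94 ± 0.33. Interferon-stimulated genes were higher in 14 of 25 (15 adjusted over the list alone), Gbp3 by 2.89 ± 0.24. All 14 B-cell markers were higher (14 adjusted over the list alone), the B-cell factor Pax5 by 6.05 ± 0.72, as were 9 of 17 myeloid markers (17 adjusted over the list alone), with Csf3r at 5.72 ± 1.02. Splenic CD4 replicate 3 held 22130 CPM of Hba-a1 and 1556 of Lyz2. Whether the B-cell and myeloid transcripts came from other spleen cells was not tested. The thymic side held transcripts of earlier stages, with 347 CPM of Il2ra in transgenic CD4SP replicate 1 and 6487 of Rag1 and 3093 of Cd8a in replicate 2, so the lower cell cycle and DP genes cannot be read as a change after export alone.

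Camera's adjusted p for these splenic CD4 lists was 7.73e-23, 1.39e-11, 2.25e-07, 1.39e-13 and 2.86e-08, lost at an adjusted p = 0.361, or 0.496 for myeloid markers, with an estimated correlation. They are part of 11 lists called upward and 7 downward in this comparison, 0 of them kept with an estimated correlation. Of 12578 genes 1575 were higher and 1510 lower, in total 3085, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 461, 656 and 1285 without splenic replicates 1, 2 and 3, 2009 with a replicate block and 2613 with the suffix term. Of 96 named genes past the threshold 37 kept it in every leave-one-out fit, the 6 named here being Cdc6, Dntt, Notch3, Gbp3, Pax5 and Csf3r.

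In splenic CD8 cells all 34 cell cycle genes were lower (34 adjusted over the list alone), with the ribonucleotide reductase gene Rrm2 at -4.82 ± 0.27, and 15 of 20 DP genes were lower and 1 higher (15 and 1 adjusted over the list alone), with Dntt at -8.33 ± 0.42. Effector and memory genes were higher in 19 and lower in 2 of 27 (20 and 2 adjusted over the list alone), the adhesion receptor Cd44 by 3.77 ± 0.31 and Ly6c2 by 6.28 ± 0.86. CD8 lineage genes were higher in 9 of 13 (10 adjusted over the list alone), the T-box factor Eomes by 6.30 ± 0.97. Mature and naive genes were higher in 16 and lower in 1 of 24 (17 and 3 adjusted over the list alone), with S1pr1, the receptor for thymic exit, at 3.90 ± 0.50. Interferon-stimulated genes were higher in 16 of 25 (18 adjusted over the list alone), with Irf7 at 2.07 ± 0.24, and B-cell markers in 11 of 14 (12 adjusted over the list alone), with Cd79a at 8.45 ± 0.84. Splenic CD8 replicate 1 held 435 CPM of Cd8a and 1384 of Lyz2. A source of the B-cell transcripts in other spleen cells was not tested. On the thymic side transgenic CD8SP replicate 3 held 1408 CPM of Cd4 and 6083 of Rag1, transcripts of DP cells, so the lower DP genes cannot be read as a change after export alone.

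Camera's adjusted p for these splenic CD8 lists was 8.57e-49, 1.58e-08, 1.29e-06, 6.96e-05, 5.85e-06, 2.75e-07 and 1.44e-09, lost at an adjusted p = 0.25, 0.27, 0.322, 0.455, 0.455, 0.25 and 0.322 with an estimated correlation. They are part of 10 lists called upward and 6 downward in this comparison, 0 of them kept with an estimated correlation. Of 12185 genes 2099 were higher and 2447 lower, in total 4546, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 2626 without transgenic CD8SP replicate 1 and 2982 without splenic CD8 replicate 2, 3242 with a replicate block and 5232 with the suffix term. Of 97 named genes past the threshold 75 kept it in every leave-one-out fit, all those named here among them.

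Between the splenic lineages, CD4 lineage genes were lower in CD8 than in CD4 cells in 5 of 13 (9 adjusted over the list alone), with Foxp3, the factor of regulatory T cells, at -6.25 ± 0.42, Tnfrsf4 at -4.33 ± 0.30 and Il2ra at -3.77 ± 0.31. Cd40lg, the helper ligand, was at -6.23 ± 0.65 and the chemokine receptor Xcr1 at 4.36 ± 0.41. Adjusted p was 0.0062, 0.0062, 0.0166, 0.0346 and 0.0264 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CD8 lineage genes were higher by camera at an adjusted p of 2.69e-09, with 0 of 13 past the threshold and 8 adjusted over the list alone, lost at an adjusted p = 0.703 with an estimated correlation, while that of the CD4 list was 2.05e-23, lost at an adjusted p = 0.258 with an estimated correlation. Between the splenic lineages camera called 1 list upward and 5 downward, and 0 were kept with an estimated correlation.

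The splenic lineage count was 61 of 12429 genes, 13 higher and 48 lower in CD8 cells. It was 0, 5 and 25 without splenic CD4 replicates 1, 2 and 3, and 1289, 1 and 0 without splenic CD8 replicates 1, 2 and 3. A replicate block gave 0 by edgeR, with 1579 at an unadjusted p under 0.05, the suffix term gave 377 and DESeq2 called 839. Of 14 named genes past the threshold none kept it in all of these fits: 0, 3 and 7 kept it without splenic CD4 replicates 1, 2 and 3, and 14, 1 and 0 without splenic CD8 replicates 1, 2 and 3.

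The ChIP libraries ask where LMO2 lies on DNA, with wild-type DN3, which has little Lmo2 RNA, as the background. Transgenic DN3 gave 2239 peaks over 140 kb, transgenic DP 1225 over 73.2 kb, splenic CD4 816 over 51.0 kb and splenic CD8 20265 over 1201 kb, and wild-type DN3 gave 724 over 41.2 kb. Median fold over background was 3.53, 3.69, 3.93, 3.47 and 3.99 in that order, and the highest was 15.1 in transgenic DN3 against 7.97 in wild-type DN3. At a q under 0.05 there were 75 peaks in transgenic DN3, 1 in transgenic DP, 8 in splenic CD4, 26 in splenic CD8 and 5 in wild-type DN3. There are no replicates and the depth of these libraries is unknown, so the numbers were not tested against each other.

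Ranked by fold, the highest transgenic DN3 peak free of a wild-type peak lay on chromosome 2 at 60240820 to 60240891 (mm9) with a fold of 15, and splenic CD4 cells had a peak there too. The next were on chromosome 1 at 12634858 to 12634932 with 13.8, chromosome 10 at 71759941 to 71760083 with 12.7, chromosome 8 at 125244369 to 125244489 with 12.1 and chromosome 2 at 16604711 to 16604768 with 12.1. In transgenic DP the highest by fold, none of which passes a q of 0.05, were on chromosome 6 at 80787557 to 80787624 with 6.11, chromosome 11 at 4767548 to 4767618 with 5.99 and chromosome 8 at 71941878 to 71941932 with 5.71, the last shared with transgenic DN3. A further pair, on chromosome 11 at 52815147 to 52815197 and chromosome 12 at 87805910 to 87805977, had a fold of 5.51 and does not pass that q either. Of the 2239 transgenic DN3 peaks 22 overlapped a wild-type DN3 peak, 0.983% (95% exact interval 0.617 to 1.48), and 19 a transgenic DP peak, 0.849% (0.512 to 1.32). Random placement gave means of 0.00536% and 0.00447%. The genes at these places were not analysed here.

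**Figure D3:**
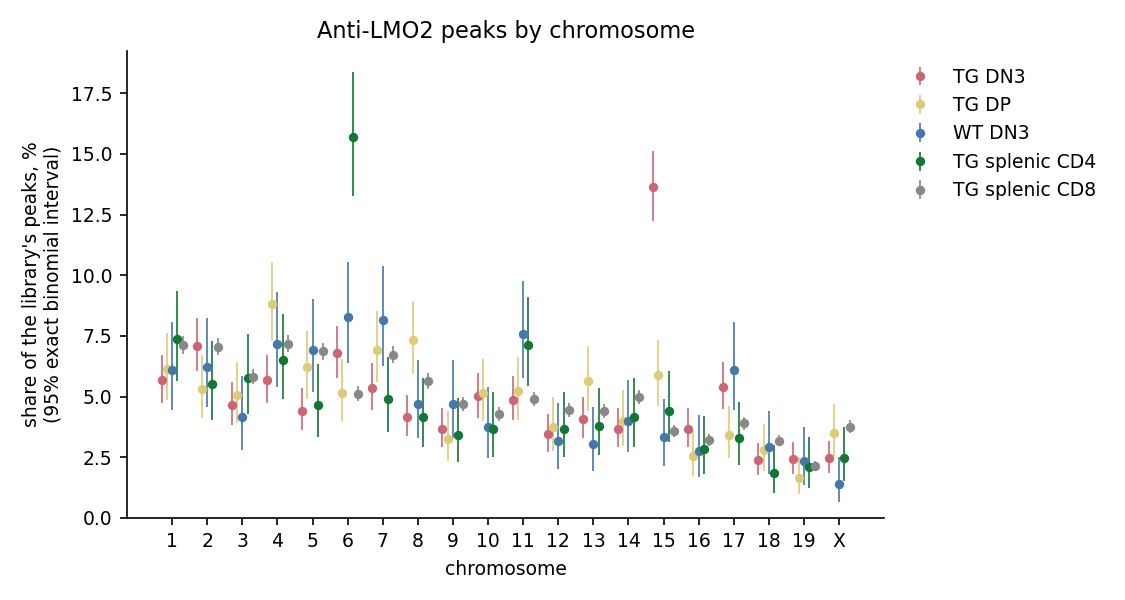
Percent of the peaks of each ChIP library on each mouse chromosome, with exact binomial 95% intervals that cover counting error only. In transgenic DN3 13.6% of 2239 peaks lay on chromosome 15, against 3.31% of 724 in wild-type DN3.

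Chromosome 15 held 305 of the transgenic DN3 peaks, 13.6% (95% exact interval 12.2 to 15.1), and 24 of the wild-type DN3 peaks, 3.31%. RNA of that chromosome was compared as the median log2 ratio to wild type of its genes minus that of other genes. In transgenic DN it was 0.584, 0.449 and 0.562 in replicates 1, 2 and 3, and in transgenic CD4SP 0.622, 0.423 and 0.556. In transgenic DN3 it was 0.209, 0.218 and 0.245, in DP 0.169, 0.632 and 0.04, and in CD8SP 0.018, 0.572 and 0.358, while wild-type libraries lay between -0.055 and 0.076. Of the genes of chromosome 15, 33.4% were called up in DN against 6.4% of other genes. The shares were 36% against 14.1% in CD4SP, 35.3% against 23.0% in DN3 and 5.87% against 1.93% in CD8SP. The increases counted at these stages therefore include this shift. Chromosome 10 stood at 0.35 in transgenic CD4SP replicate 2. Chromosome 13 stood at -0.241 in transgenic DN replicate 3, -0.246 in DP replicate 1 and -0.252 in CD4SP replicate 3, but wild-type DP replicate 1 was nearly as low, at -0.23.

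**Figure D4:**
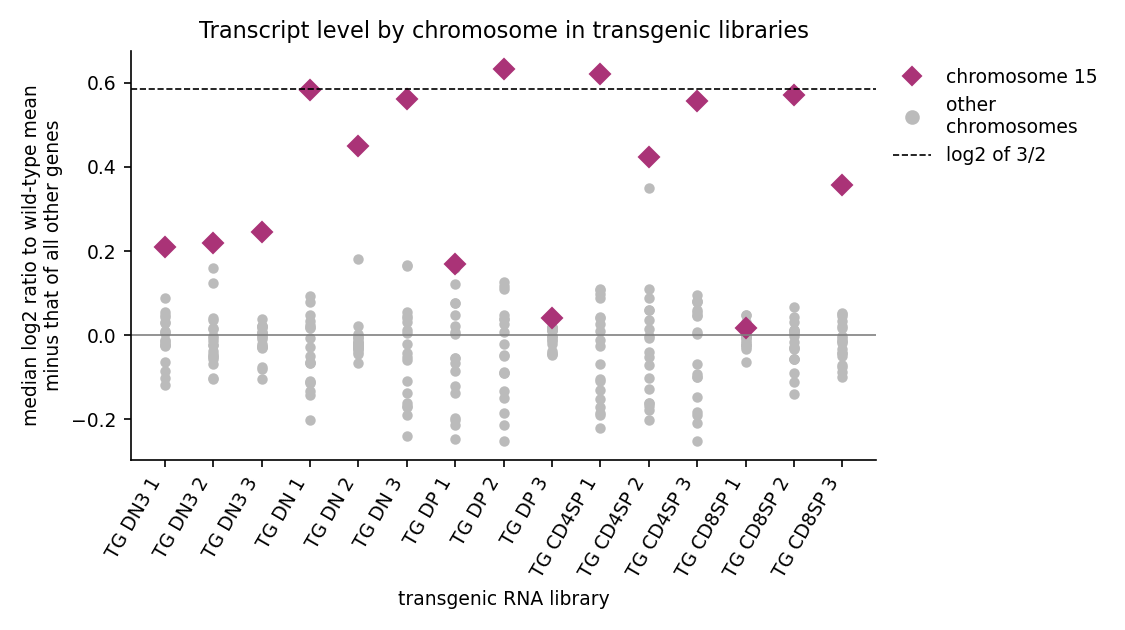
Median log2 ratio to wild type of the genes of each chromosome minus that of other genes, 1 point per library. Chromosome 15 of transgenic DN lies at 0.584, 0.449 and 0.562, chromosome 10 of transgenic CD4SP replicate 2 at 0.35 and chromosome 13 of several transgenic libraries down to -0.252. Autosomes of wild-type libraries lie between -0.23 and 0.139, both ends on chromosome 13 in DP.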

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

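The tests on transgenic DP replicate 3, on a batch marked by the letter N, on dense windows of peaks and on other splits of the samples were chosen only after the result each concerns was seen. The groups hold 1 or 3 libraries, too few for a test of single libraries against their group.

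The genotype effect differed between DN3 and DP for 1266 genes by the interaction term. Positive interactions, meaning a log2 fold change higher in DP than in DN3, were 8.26 for Arhgef10l, 7.47 for Cdkn1a, 7.35 for Bst1, 6.93 for Adam11 and 6.57 for Cdh1. They need not mean a larger effect in DP, where no gene passed alone. Adam11 stood at -7.19 in DN3 and -0.27 in DP, and Cdh1 at -3.80 and 2.77. Negative ones were -5.49 for Slc40a1, -5.27 for St8sia6, -4.98 for F2r, -4.21 for Adcy9 and -3.85 for Shc4. Of 100 splits of the 12 libraries, the real one included, 3 gave as many genes, and the highest of the others gave 5233. This share cannot exclude chance, since the count follows the labels of DN3: the 10 other splits that kept them called between 402 and 5233 genes, 2 of them more than the real split, and all splits that changed them called 0 or 1. The number of splits was also set to 100 after a smaller first set had been seen. The split that called 5233 genes, several times the real count, kept the labels of DN3 and changed those of 4 of the 6 DP libraries. Such a change turns the difference of the genotype effects towards their sum, so its count does not measure chance. A structure of the samples was not tested. Without transgenic DP replicate 3 the count was 2598, and Bst1, Slc40a1 and St8sia6 lost their call in some leave-one-out fits.

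Between CD4SP and CD8SP the effect differed for 4 genes, with interactions of 1.96 for Zfp281, -3.50 for Mcoln2 and -2.75 for Cxxc5. Of 100 splits 8 gave as many genes and the highest of the others gave 4696, so chance cannot be excluded. That highest split kept the labels of CD4SP and exchanged those of all 6 CD8SP libraries, which adds the 2 genotype effects instead of subtracting them. The further splits with as many genes, which called from 162 to 2992, also kept the labels of CD4SP. Such splits hold real genotype effects, so their share does not measure chance, and they do not show a structure of the samples. None of these calls was kept without wild-type CD4SP replicates 1 or 2 or without wild-type CD8SP replicates 1 or 3.

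For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split and the highest other gave 5497 and 0 genes in DN3, 1547 and 0 in total DN, 3132 and 0 in CD4SP, 520 and 0 in CD8SP, 3085 and 0 for splenic CD4, 4546 and 0 for splenic CD8, and 61 and 0 between the splenic lineages, with 1 split of 10 as large each. In DP all 10 of 10 splits gave 0 genes by edgeR, where 2450 had an unadjusted p under 0.05 and DESeq2 called 605.

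Transgenic DP replicate 3 held 11 reads of Lmo2, 0.395 CPM. The highest wild-type DP library had 0.472 CPM, which argues against an exchange with one of them, and the Y-linked gene Ddx3y was at 0.0359 CPM in this library, 37.6 and 55.6 in the other transgenic DP libraries and 80.4, 217 and 172 in wild-type DP. Over the 906 genes called without this library, places were taken on a scale from wild type (0) to the other transgenic DP libraries (1). Wild-type DP replicates 1, 2 and 3, each left out of the wild-type mean in turn, had median places of 0.161, -0.077 and -0.097. Transgenic DP replicate 3 had a median place of 0.196, above all 3, with quartiles of 0.045 and 0.371. This argues against transgenic cells that lost the transgene's RNA and kept the rest of their state, and it is consistent with cells without the transgene under this label. A transgene switched off with the rest of the state reverting stays open.

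Hhex, Lyl1 and Kit were high in those transgenic DP, CD4SP and CD8SP libraries whose column names end in N, with Hhex at 24.0 CPM in DP replicate 2, 171 and 67.2 in CD4SP replicates 1 and 3, and 26.3 in CD8SP replicate 2. The wild-type libraries with that letter had at most 0.331 CPM of Hhex, which argues against a batch that raises these genes in both genotypes. DN cells in the sort could also bring them, and other DN3 transcripts would then imply a like share of DN cells: they implied at least 0.5 times that share in 2 of 4 libraries, the ratios being 0.419, 0.462, 0.736 and 0.737. These transcripts implied 7.82% of DN cells in DP replicate 2, 63.1% and 39.2% in CD4SP replicates 1 and 3 and 14.9% in CD8SP replicate 2, while in CD4SP replicate 1 Kit implied 44.5%, and Hhex and Lyl1 implied 137% and 228%, more than DN3 levels can give. DN cells and higher expression in the sorted cells themselves therefore cannot be told apart, as the libraries divide on this test.

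Chromosome 15 held 13.6% of transgenic DN3 peaks and its transcripts were raised in most transgenic thymic libraries. The 5 fullest windows of 1 Mb held 16.4% of the chromosome's peaks and the strong peaks had 11.2% on this chromosome, which argues against a few windows or weak calls as the source. The same median between wild-type stages was at most 0.081 in size, which argues against stage composition. In total DN, for which this test was set, the lowest of 5 segments of the chromosome stood at 0.414, which a gain of the whole chromosome there could give. The lowest was 0.321 in CD4SP, 0.226 in CD8SP, 0.099 in DN3 and 0.049 in DP, which leaves such a gain open at these stages. Each is a mean over libraries, and these differ in DP and CD8SP. In DN3 the libraries were alike, at 0.209, 0.218 and 0.245. There segments 2 and 3 stood at 0.099 and 0.116, and segments 1, 4 and 5 at 0.267, 0.315 and 0.276. In the RNA of DN3 the highest library reached 0.245, where 0.585 is the log2 ratio of 3 copies to 2, so whether the cells of the ChIP library carried such a gain stays open. A gain in leukaemic or preleukaemic clones may be the source, as a hypothesis found and tested on the same data, and Myc, an oncogene on this chromosome, was not called at any stage.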

How the results depend on the processing

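The fits with a term for the letter N and those without libraries in doubt were chosen only after the data were seen. Of 7831 values of named genes and lists under the alternatives, 6335 kept their direction and their side of the threshold, 1481 lost the call, 4 gained it and 10 moved. Only Tyrobp in CD4SP reversed, to -0.06 with the suffix term. Of 173 results of comparisons, 86 stayed within 1.5 times their value. The cause of the shifts below was not tested, except that fits without a library have fewer samples.

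With DESeq2 the counts were 2632 in DN, 605 in DP, 1248 in CD8SP, 3 in DN1, 2295 between DN3 and DP, 694 between CD4SP and CD8SP, 839 between the splenic lineages and 105 shared by the 5 stages. One fit of all RNA libraries gave 2644 in DN3, 695 in DP, 5723 in CD4SP, 553 between DN3 and DP, 500 between CD4SP and CD8SP, 6867 for splenic CD4, 7722 for splenic CD8, 1164 between the splenic lineages and 79 shared by the stages. A fit of DN1, DN3 and total DN gave 4 in DN1. A replicate block gave 1362 in CD4SP, 798 in CD8SP, 2009 for splenic CD4, and by edgeR 0 between CD4SP and CD8SP (1841 at an unadjusted p under 0.05, DESeq2 694) and 0 between the splenic lineages (1579 and 839). In no comparison did all pairs of equal replicate number correlate above 0.1. The suffix term gave 198 in DN, 1991 between DN3 and DP, 1 between CD4SP and CD8SP and 377 between the splenic lineages. The branch difference was 32 with no filter and 11 at a mean CPM of 1.

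Without libraries in doubt the counts were 888 in DN (wild-type replicate 3) and 483 in CD8SP (replicate 3 of both genotypes). For CD4SP and the CD4SP to CD8SP difference, leaving out transgenic CD4SP replicates 1 and 2 left 1 transgenic CD4SP library. No counts are given for these. The splenic CD4 fit, also without splenic CD4 replicate 3, rests on that 1 transgenic CD4SP library too. Its number cannot be set against the main fit, and no conclusion is drawn from it. The numbers for the spleen and for the shared genes follow. They were 6278 for splenic CD4, 6324 for splenic CD8, 4494 between the splenic lineages (without splenic CD4 replicate 3 and CD8 replicate 1) and 105 shared by the stages without transgenic DP replicate 3. List tests called 102 in all with the preset correlation, 0 with an estimated one and 53 with fry. A replicate block ended the calls of mast-cell markers in DP (0.0775), CD8 lineage genes between CD4SP and CD8SP (0.0739) and CD4 lineage genes in splenic CD4 cells (0.0645), adjusted p in brackets. It added LMO2 partners (0.0144) and mature genes (0.01) in DN3, gamma-delta markers in DN (0.0409), mast-cell (0.0226) and pre-TCR genes (0.0477) in CD4SP, DP genes in CD8SP (0.00925), erythroid (0.00488) and V(D)J genes (0.0473) between the branches and dendritic-cell markers in splenic CD8 cells (0.0252). Peaks at a -log10 p of 5 or more were 385 in transgenic DN3, 113 in DP, 76 in wild-type DN3, 94 in splenic CD4 and 3692 in splenic CD8.

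Leaving out 1 library gave 3802 to 6185 genes in DN3, 179 to 3146 in DN, 0 to 906 in DP, 38 to 4329 in CD4SP, 9 to 724 in CD8SP, 0 to 0 in DN1, 352 to 2598 between DN3 and DP, 0 to 611 between CD4SP and CD8SP, 461 to 3227 for splenic CD4, 2626 to 5354 for splenic CD8 and 0 to 1289 between the splenic lineages. Shares of peaks at start sites, motif shares and the joining of peaks to changed genes were not run, as no mm9 genome or annotation was used. With 3 libraries a group, simulated log2 changes of 1 were found in 83% of cases in DN3, 43% in DN, 40% in DP, 7% in CD4SP and 34% in CD8SP, and those of 2 in 96%, 77%, 84%, 70% and 89%.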

Other observations

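The window of chromosome 6 was chosen only after its values were seen, and the tests of neighbouring genes were stated before theirs were. In transgenic CD4SP single members changed of lists that camera did not call. Among genes of V(D)J recombination and joining Xrcc6, the Ku70 subunit of end joining, rose by 3.15 ± 0.36 and the damage kinase Atm fell by 1.2 ± 0.28. p53 targets held Gtse1 at 3.52 ± 0.39 and Phlda3 at 3.39 ± 0.59, and apoptosis regulators Bmf at 3.39 ± 0.64 and Bid at 1.78 ± 0.30. Xrcc6 was also up by 1.12 ± 0.22 in CD8SP, and lower by -3.64 ± 0.33 and -3.87 ± 0.29 in splenic CD4 and CD8 cells than in their thymic counterparts. Adjusted p of these values was between 0.000597 and 0.0357 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, but in CD4SP none was kept without wild-type replicate 1, and in CD8SP Xrcc6 kept it in 2 of 6 such fits.

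Some single genes also differed between spleen and thymus. The platelet integrin Itga2b was higher by 5.72 ± 0.61 in splenic CD4 and 4.55 ± 0.73 in splenic CD8 cells. Klrd1, a receptor of NK and memory CD8 cells, was higher by 4.80 ± 0.41 in splenic CD8 cells, and Bcl2, which protects from cell death, by 2.77 ± 0.48. Gzma, a granzyme gene, was lower at -3.94 ± 0.29. Adjusted p was 0.00628, 0.00524, 0.000771, 0.00658 and 0.000537 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each call was kept whichever library was left out.

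Genes changed at least 8-fold in DN3 lay next to each other in the genome more often than random genes. Of 213 such genes that rose, 35 had another beside them among the genes tested, where 10000 random lists gave a median of 8 and a 95th percentile of 14. Of 196 that fell, 40 did, where random lists gave 6 and 12. The permutation p was 1e-04 for both, the smallest these lists can give. The longest run among those that fell was Hoxa3, Hoxa4, Hoxa5, Hoxa7 and Hoxa9 on chromosome 6. What links neighbouring genes was not tested.

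In the ChIP lists, a window of chromosome 6 from 47601771 to 47728270 (mm9) held 73 of the 816 splenic CD4 peaks, 20 of the transgenic DN3, 19 of the wild-type DN3, 1 of the transgenic DP and 5 of the splenic CD8 peaks. The place is dense in wild-type DN3 too. Chromosome 6 as a whole held 15.7% of the splenic CD4 peaks (95% exact interval 13.3 to 18.4).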
